A study of Arabidopsis thaliana with 3 samples.

How the data were processed

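Genomic DNA from 9-day-old Arabidopsis thaliana Col-0 seedlings, grown under a 16 h photoperiod, was sheared to about 300 bp. It was immunoprecipitated with an antibody against N6-methyladenine (6mA), a methylated form of the DNA base adenine, per the labels' protocols. The series held 3 samples: 1 input library of sheared DNA without immunoprecipitation, and 2 immunoprecipitated replicates. Paired-end sequencing followed, per the labels' protocols. The labels do not say whether the replicates came from separate cultures, so the spread between them may be technical.

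Reads were trimmed with Trim Galore and the genome build was TAIR10, per the submitters' processing notes. The aligner was not given in the sources used here. Peaks were called with MACS 2.2.6 in paired-end mode, per the file headers, separately for each immunoprecipitated library against the same input library and not on pooled replicates. The effective genome size was set to 135 Mb and the q cutoff to 0.05. At most 1 fragment was kept per position, and the larger library was scaled towards the smaller. The pileup column of the deposited lists is a signal value, the coverage by fragments at the summit, per the file headers. The −log10 p-value and −log10 q-value columns come from the caller's comparison with the input, per the file headers. The fold enrichment is a linear ratio of pileup to local input background in the authors' deposited lists. A peak with several summits took the values of its summit with the highest fold. No list of the input library was used here, so it entered only through the caller's comparison.

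The depth came from the file headers. After removal of duplicates, replicate 1 held 28141317 fragments of 36775906, replicate 2 held 995366 of 1971564, and the input held 61231606 of 105432068. The caller's fold was taken as pileup plus 1 over background plus 1, which gave the background implied at each summit. In replicate 2 the lowest implied background, 1.78, recurred at 8 summits within 0.001 and lay beside the mean coverage of 1.77. At 67 pairs of nuclear summits within 50 bp of each other, the implied background over mean coverage of replicate 1 was 1.00 times that of replicate 2 (median; range 0.953 to 1.11). Folds of both lists were therefore compared as ratios to the same input.

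Samples were grouped by their titles. No treatment was compared, so the comparisons were between replicates and between peaks and the genome. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. The number shared was set against 10000 random placements of the other list within each chromosome (one-sided permutation p, smallest possible value 0.0001). Strength agreement was tested over shared regions with Spearman and Pearson correlations of log fold and 100000 permutations, two-sided. Because both lists share 1 input, 1000 simulations drew unchanged libraries against a common Poisson input. No such simulation was possible for the overlap of peaks, which would need the reads, so part of that overlap may come from the shared input. Peaks per chromosome were tested with two-sided exact binomial tests against chromosome length, with Benjamini-Hochberg adjustment over 5 chromosomes. Shares of region midpoints were set against 10000 random placements (two-sided permutation p, smallest possible value 0.0002). Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only.

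The region set was to be the regions covered by both lists if there were at least 30 of these. There were 27, so the set was the union of both lists, 161 nuclear regions. Pericentromeres were the runs of 100 kb windows around the lowest protein-coding gene density, smoothed over 1 Mb, where density was below 50% of the chromosome's median, 17.2 Mb in all. Genes came from a RefSeq table of assembly TAIR10.1, with 27444 nuclear protein-coding genes. The peaks are in TAIR10 coordinates. The table served for gene names, gene density and overlap with genes, on the assumption that both assemblies share nuclear and plastid positions, and none of its coordinates is printed. As a check, the overlap of replicate 2 plastid peaks with plastid rRNA genes was largest at shifts of -130 to -80 bp in a search of 5000 bp either way. The simulations with a common input, the plastid position check and the depth limit below were not part of the plan. The overlap, strength, chromosome, share and gene list tests were fixed before the data were examined. So were 39 of the 56 alternatives used and the rule for named regions. The rule took the 10 strongest nuclear peaks of each list by fold, the 5 strongest of each list absent from the other, up to 4 genes of each gene list past its test, and any N6-adenine methylation gene under a peak. Other named regions and all plastid genes were chosen after their values were seen.

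The gene lists were matched on symbols and synonyms, since the table has no description text, which leaves several lists short. They were cytosolic ribosomal proteins, light harvesting and photosystem proteins, histones, heat shock proteins, F-box proteins, pentatricopeptide proteins, cytochrome P450, receptor-like and leucine-rich repeat kinases, NLR disease resistance, extensins and wall proteins, auxin, WRKY, MYB, bHLH and NAC factors, tRNA, rRNA, snoRNA with snRNA, and N6-adenine machinery. The table held 0 transposable element genes, so that list was not tested. Genome sequence, exons and strand were not used here, so A+T content, motif density, tandem repeats and distance to transcription starts were not analysed here. Annotation classes were reduced to protein-coding genes, other genes and the bases between genes, and random placements could not avoid runs of N.

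Peaks of either list under 100 kb apart were joined into loci. To set a limit from depth, each peak was assumed to have the same fold in the other library, and its implied background was scaled to that library's mean coverage. The smallest callable fold was the one whose Poisson p reached the weakest p in that library's list. The tests were checked on simulated lists. Of 200 scattered lists with no shared position, 3 passed the overlap test at 0.05, and all 200 lists with 9.46% of positions planted passed, with 9.57% recovered. For the pericentromeric share over 161 regions, 11 of 200 scattered lists passed by single placement. When the real list was rotated as a whole, which keeps its clusters, 152 of 200 passed by single placement and 5 of 200 by rotation. Rotation was therefore added after the data were seen, as an alternative for overlap, shares and gene lists. Of 200 simulated sets of 27 regions with a correlation of 0.6, 174 passed. For gene lists, 0 of 380 tests on scattered regions passed. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Alternatives tried were the overlap rule, stricter peaks, local placement, each list alone, other region sets, another pericentromere definition, summits for midpoints and regions outside pericentromeres.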

Results

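N6-methyladenine (6mA) in the DNA of Arabidopsis thaliana Col-0 seedlings was profiled by antibody pull-down and sequencing, in 2 immunoprecipitated replicates and 1 input library. Depth differed widely. Replicate 1 kept 28141317 fragments after removal of duplicates and replicate 2 kept 995366, so replicate 1 was 28.3 times deeper. Duplicates made up 23% of the fragments of replicate 1, 50% of replicate 2 and 42% of the input. Replicate 1 had 146 peaks, 74 in nuclear chromosomes and 72 in the plastid chromosome. Replicate 2 had 149 peaks, 139 nuclear and 10 plastid. Nuclear peaks covered 38.7 kb in replicate 1 and 157 kb in replicate 2. All peak positions are in TAIR10, and each fold is the authors' enrichment of a peak over the shared input.

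The first comparison asked whether the replicates marked the same nuclear positions. The nuclear peaks of both lists fell into 17 loci, and 9 of these held peaks of both replicates, with 69 of the 74 peaks of replicate 1 and 134 of the 139 of replicate 2. These counts rest on joining peaks under 100 kb apart, had no test against random loci, and include 80 replicate 2 peaks in 4 stretches of chromosomes 4 and 5 with 0 replicate 1 peaks. The shared loci with the highest folds lay on chromosome 4 at 3950517 to 4011694, on chromosome 3 at 13586922 to 13709993, on chromosome 2 at 3605681 to 3718382 and on chromosome 5 at 11664796 to 12065252. Others lay on chromosome 1 at 15081949 to 15086043, chromosome 5 at 11184583 to 11187884 and chromosome 4 at 2920745 to 3061205. The remaining pair held nuclear rRNA genes, at the start of chromosome 2 (1296 to 10310) and on chromosome 3 (14191861 to 14216405). Of the replicate 1 nuclear peaks, 52 of 74 overlapped a replicate 2 peak (70.3%, exact 95% interval 58.5 to 80.3), against 0.227% in random placements (permutation p = 0.0001, the smallest possible). In the other direction 27 of 139 overlapped (19.4%, exact 95% interval 13.2 to 27.0, against 0.111%, permutation p = 0.0001). The 87 summits of replicate 1 in shared peaks lay a median of 13 bp from the nearest replicate 2 summit, against 85 bp for random positions in the same peaks (permutation p = 0.0001). Replicate 2 peaks were wider, and with a reciprocal overlap of at least 50% only 2.70% of replicate 1 peaks and 1.44% of replicate 2 peaks counted as shared (permutation p = 0.0006 and 0.0003). With placement within 1 Mb, the random shares were 2.02% of replicate 1 and 1.08% of replicate 2 peaks (permutation p = 0.0001 for both). Shared peaks stood on an implied input background of at least 19.1 times the mean coverage in replicate 1 and 36.8 times in replicate 2. Random placements did not match this background, so the excess overlap cannot be told apart from deep input. Both lists were called against the same input, which can itself bring peaks to the same positions.

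**Figure D1:**
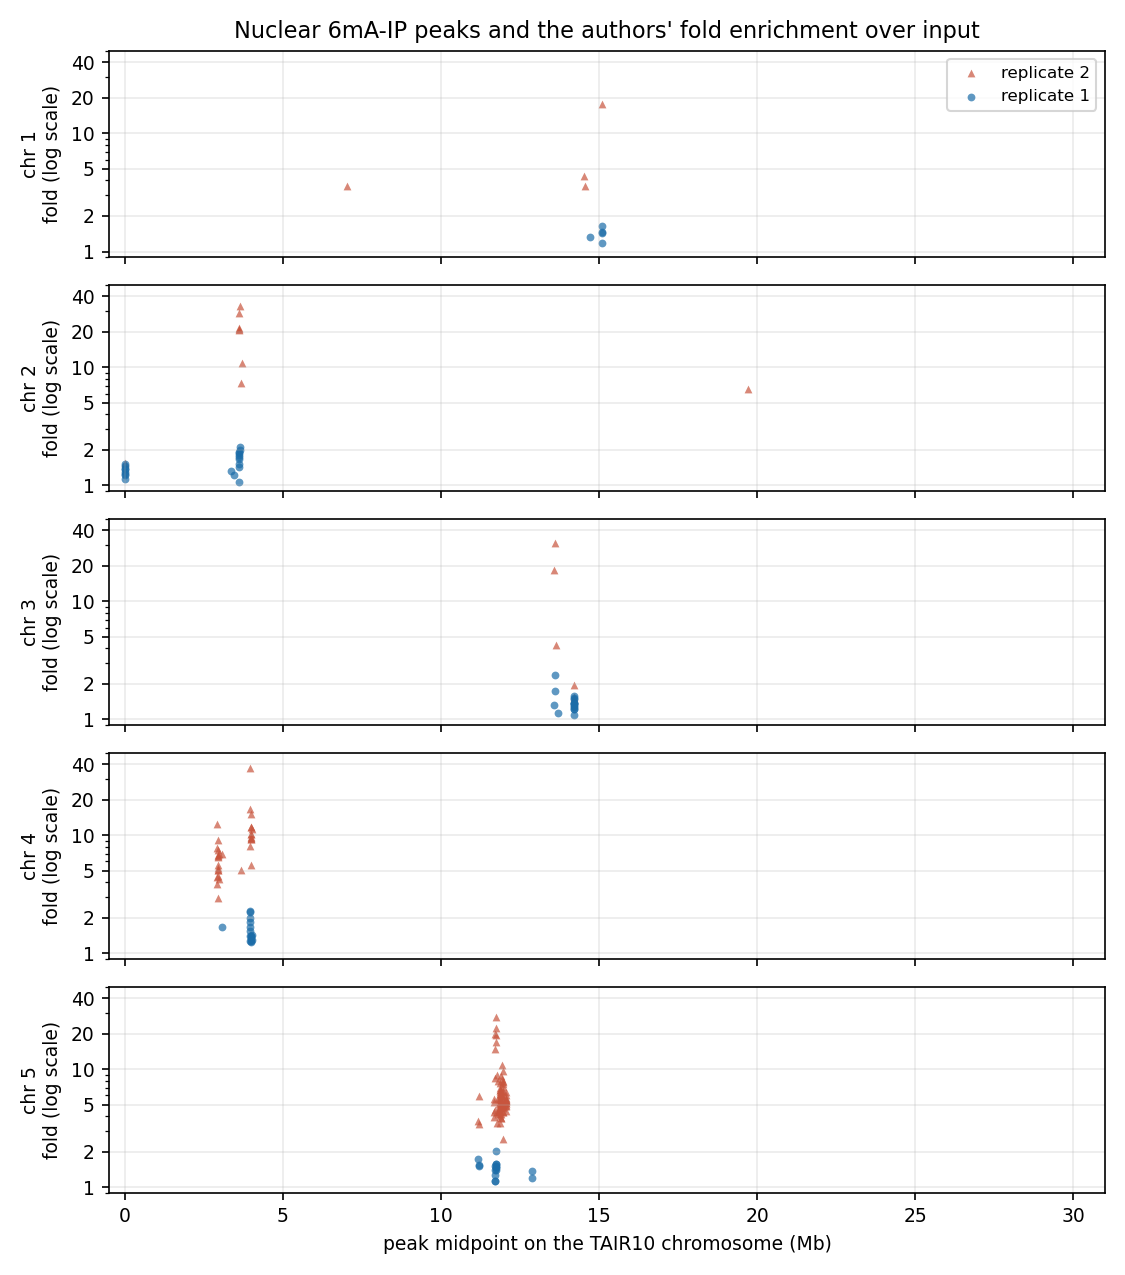
Nuclear peaks of replicate 1 (circles) and replicate 2 (triangles) on chromosomes 1 to 5. The x axis is the TAIR10 position in Mb and the y axis the authors' fold enrichment over input on a log scale, 1 point per peak. Peaks crowd into 17 loci, and the highest fold is 2.38 in replicate 1 and 37.3 in replicate 2.

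The loci found in 1 replicate held few peaks. Replicate 1 alone had 5 peaks in 4 loci, on chromosome 1 at 14721321 to 14721526 (fold 1.32), chromosome 2 at 3356795 to 3357048 in the pseudogene AT2G07697 (1.32), chromosome 2 at 3458966 to 3459349 in AT2G07656 and the pseudogene AT2G07729 (1.22), and chromosome 5 at 12877520 to 12886736 (1.21 and 1.36). Replicate 2 alone had 5 peaks in 4 loci. These were chromosome 1 at 14508311 to 14544755, a span of 36.4 kb with 2 peaks (3.56 and 4.32), chromosome 4 at 3655475 to 3655954 in the pseudogene AT4G06597 (5.04), chromosome 2 at 19697755 to 19698284, 0.934 kb from AT2G48160 (fold 6.56), and chromosome 1 at 7025049 to 7025314, 0.234 kb from AT1G20290 (fold 3.60 at a pileup of 9). These loci were chosen after their values were seen. Among peaks absent from the other list, the strongest of replicate 1 covered the rRNA genes AT3G41768 and AT3G41979 on chromosome 3 (14198974 to 14202272, fold 1.57). It was followed by peaks on chromosome 2 at 1296 to 1545 in AT2G01008 (1.51), on chromosome 3 at 14194547 to 14195201 near AT3G41762 (1.48), on chromosome 2 at 9850 to 10310 in AT2G00340 (1.46) and on chromosome 3 at 14212445 to 14212955 in AT3G00670 (1.39). The strongest of replicate 2 lay on chromosome 2 at 3614914 to 3615393 in AT2G07981 (21.7), on chromosome 3 at 13586922 to 13587803 near AT3G33055 (18.4), on chromosome 4 at 2921574 to 2921903 near AT4G05610 (12.5), on chromosome 5 at 11928311 to 11929695 near AT5G32280 (10.9) and on chromosome 2 at 3718029 to 3718382 near AT2G09860 (10.9). If a peak had the same fold in both replicates, the depth of replicate 1 could have called all 112 nuclear peaks found in replicate 2 alone, and the depth of replicate 2 could have called 12 of the 22 found in replicate 1 alone. At shared regions folds were not the same, with replicate 1 lower by a median of 10.6 times. At the 112, the smallest callable fold in replicate 1 was 1.48 (median, range 1.05 to 1.66), against replicate 2 folds of 2.56 to 21.7. By this estimate depth did not hide folds as high as those of replicate 2. Weaker enrichment in replicate 1 could still have gone uncalled.

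Peak strength was then compared between replicates. The strongest peak of replicate 1 lay on chromosome 3 at 13591085 to 13592446, 7.11 kb from AT3G33055 (fold 2.38), inside a replicate 2 peak with fold 31.2. The strongest peak of replicate 2, on chromosome 4 at 3950517 to 3956026, had fold 37.3 and spanned 3 of the 10 strongest nuclear peaks of replicate 1 (folds 2.01 to 2.29). It overlapped the pseudogene AT4G06700, but its summit lay outside, in a replicate 1 peak 2.80 kb from that pseudogene. The gene AT2G08986 on chromosome 2 carried 3 of the 10 strongest of replicate 1, at 3620879 to 3621296 (1.88), 3622509 to 3622723 (1.91) and 3625677 to 3626431 (2.01). The replicate 2 peaks that overlapped that gene reached 28.7 at 3617942 to 3624002 and 32.9 at 3624249 to 3627572. The summit with 32.9 lay outside the gene, in a replicate 1 peak 0.44 kb from it. On chromosome 5 the replicate 1 peak at 11732138 to 11732630, 6.65 kb from AT5G31821, had fold 2.02 and the replicate 2 peak around it 27.6. The others among the 10 strongest of replicate 1 lay on chromosome 2 at 3626900 to 3627411 (2.10) and chromosome 4 at 3966438 to 3966644 (1.86). Those of replicate 2, besides the peak in AT2G07981 at 3614914 to 3615393 (21.7) that replicate 1 lacked, lay on chromosome 5 at 11734456 to 11736317 (22.4) and 11706203 to 11709376 (19.7), and on chromosome 2 at 3605681 to 3607850 (21.3) and 3615722 to 3617541 over AT2G07981 (20.7). Fold was higher in replicate 2 in 27 of 27 shared regions, by a median of 10.6 times (range 1.08 to 16.3, SD 5.02). At the 4 regions within 10 kb of a nuclear rRNA gene the ratio was 1.27 (median, range 1.08 to 1.28), and at the other 23 it was 10.9 (median, range 2.08 to 16.3).

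Across these 27 regions, which are not independent replicates, folds were correlated (Spearman's rho 0.63, permutation p = 0.00069, and Pearson's r of log fold 0.55, permutation p = 0.0029). Unchanged libraries simulated against a common input gave a median rho of 0.07, and the central 95% of them reached up to 0.47. The covariance was 0.100 against 0.000104 in the simulations. The simulations drew a single value per region and library and left out peak calling. Each measured fold was instead the highest in its region, so wide regions can be high in both lists. Regions also share loci. The simulations therefore cover counting noise in the shared input only and give no chance level for the measured rho. The single input could not be split, so part of the correlation may come from it.

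**Figure D2:**
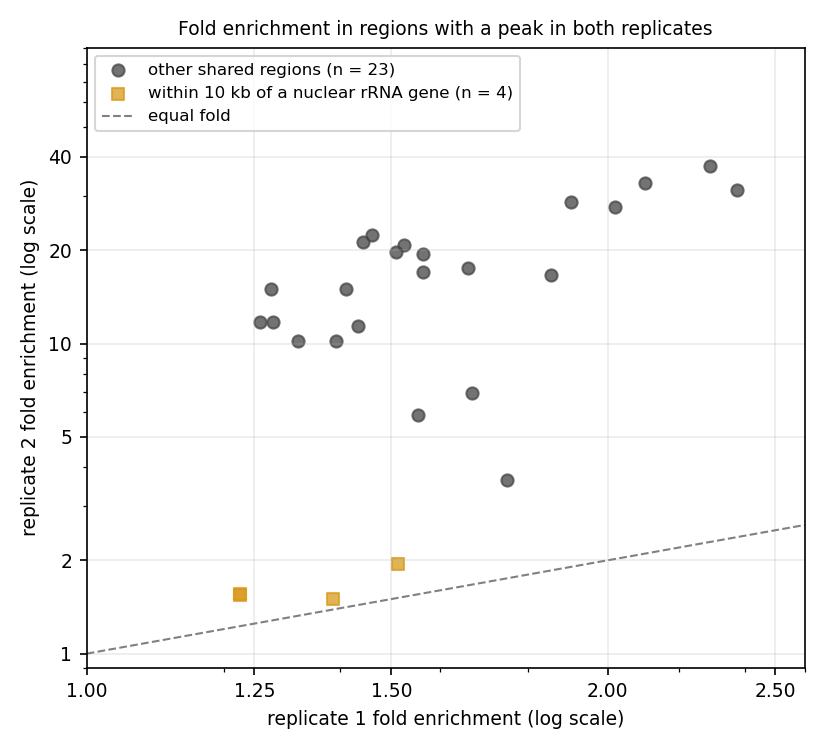
Fold enrichment of the 27 nuclear regions with a peak in both replicates, replicate 1 on the x axis and replicate 2 on the y axis, both log scales, 1 point per region. Squares are the 4 regions within 10 kb of a nuclear rRNA gene, which lie near the dashed line of equal fold, and circles are the other 23, with a median ratio of 10.9.

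The next comparison placed the 161 nuclear regions of the merged lists along the chromosomes. Pericentromeres, the gene-poor DNA around centromeres, held 142 of the 161 (88.2%, exact 95% interval 82.2 to 92.7), against 14.7% in random placements (permutation p = 0.0002, the smallest possible). The interval takes regions as independent, which clustered regions are not. When loci were counted in place of regions, 64.7% of the 17 lay in pericentromeres, against 13.8% in random placements (permutation p = 0.0002). With the whole list of regions rotated, which keeps them clustered, the permutation p was 0.0014. The pericentromeric share was 73.0% of the 74 peaks of replicate 1 and 92.8% of the 139 of replicate 2. Nuclear peaks of replicate 1 stood on an implied input background of 135 times the mean coverage (median, range 3.88 to 465). For those of replicate 2 it was 2.09 times (median, range 1.00 to 451). Random placements did not match this background, so where it was high, position cannot be told apart from deep input. The chromosome 2 locus at 3605681 to 3718382 fell outside by the 50% rule for gene density and inside at 75%. By the 75% rule, the 8 peaks of replicate 1 left outside were all at the start of chromosome 2, beside rRNA genes. Replicate 2 had 3 outside, 1 at that same place and the peaks at 7025049 on chromosome 1 and 19697755 on chromosome 2.

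Chromosome 5 held 89 of the 161 regions against 36.4 in proportion to its length (exact binomial test, adjusted p = 1.8e-18). Chromosome 1 held 5 against 41.1 (exact binomial test, adjusted p = 3.6e-14) and chromosome 3 held 16 against 31.7 (exact binomial test, adjusted p = 0.0023). The deficit on chromosome 3 came from replicate 2, with 6 peaks against 27.4 (exact binomial test, adjusted p = 4.7e-07). Replicate 1 had 16 of 74 there against 14.6 and did not pass (exact binomial test, adjusted p = 0.83). Chromosomes 2 and 4, with 18 and 33 regions, did not pass (exact binomial test, adjusted p = 0.089 and 0.10). On chromosome 5, replicate 2 alone had 87 of its 139 peaks (exact binomial test, adjusted p = 4.1e-23), and replicate 1 alone had 17 of 74 and did not pass (exact binomial test, adjusted p = 0.89). A single locus there, at 11664796 to 12065252, held 84 of the replicate 2 peaks and 12 of the replicate 1 peaks. The binomial test takes regions as independent, which regions clustered in this way are not. When the 17 loci were counted in place of regions, 0 chromosomes passed.

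Protein-coding genes held few regions. The midpoints of 11 of 161 regions lay in a protein-coding gene (6.83%, exact 95% interval 3.46 to 11.9), against 54.2% in random placements (permutation p = 0.0002), and 85.7% lay between annotated genes against 35.7% (permutation p = 0.0002). The gene table held 0 transposable element genes, so any such genes count here as bases between annotated genes. The share in protein-coding genes depended on the list, at 21.6% of the 74 peaks of replicate 1 and 5.04% of the 139 of replicate 2. In the 27 regions covered by both lists it was 18.5%. Peaks of either list overlapped 9 of 27444 nuclear protein-coding genes. Both lists touched AT1G40104, AT2G07981 and AT2G08986. Replicate 1 also touched AT2G01008, AT2G01021, AT2G07656 and AT3G41762, and replicate 2 AT1G38790 and AT4G05612. When regions were placed at random within 1 Mb of their own position, 9.92% lay in genes and the difference did not pass (permutation p = 0.1868). Among the 19 regions outside pericentromeres, 36.8% lay in genes against 50.0% (permutation p = 0.3706), and 36.8% lay between genes against 37.7% (permutation p = 1), so neither difference passed there and the latter changed direction.

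Nuclear rRNA genes were the only gene list past its test. The 18S rRNA genes AT2G01010 and AT3G41768 and the 5.8S rRNA genes AT2G01020 and AT3G41979, 4 of 4 in the list, overlapped a region against 0.0056 in random placements (permutation p = 0.0002, adjusted p = 0.0038 over the 19 lists). All 4 were under replicate 1 peaks, with folds of 1.09 to 1.57, and 0 of 4 under a replicate 2 peak. The 18 replicate 1 peaks within 10 kb of these genes stood on an implied input background of 170 to 343 times the mean coverage, which random placements did not match. In the chromosome 2 copy, replicate 2 had a peak at 5999 to 6246 (fold 1.56) that overlapped no annotated gene but lay 0.054 kb from AT2G01020. That distance is smaller than the shifts of -130 to -80 bp in the plastid position check, but nuclear positions were not checked. The other 18 of 19 lists had 0 members in a region. These were 232 cytochrome P450 genes, 147 MYB, 140 auxin, 100 NAC, 72 WRKY, 31 bHLH and 31 F-box genes, 77 receptor-like kinases, 13 NLR genes, 54 wall proteins, 52 heat shock proteins, 52 photosystem and light harvesting proteins, 48 ribosomal proteins, 20 histones, 12 pentatricopeptide proteins, 625 tRNA genes and 369 snoRNA and snRNA genes. The last was the set of 9 N6-adenine machinery genes, which include the RNA adenosine methyltransferase genes MTA and MTB. Several lists were short because they rest on symbols. The highest random expectation among these 18 lists was 1.03 genes, for cytochrome P450, where 0 members gave a permutation p of 0.7453, so a deficit could not have passed the test.

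The plastid chromosome was compared apart. Plastid peaks made up 49.3% of the peaks of replicate 1 and 6.71% of those of replicate 2. Folds were 1.05 to 1.22 in replicate 1 (median 1.13, n = 72 peaks) and 1.36 to 2.67 in replicate 2 (median 1.68, n = 10 peaks). All 10 replicate 2 peaks lay in the inverted repeat, a stretch of plastid DNA held in 2 copies, and had a mirror peak in the other copy. They are therefore not 10 independent sites, here or in the overlap below. The positions did not coincide more than at random. Of the replicate 1 peaks, 9 of 72 overlapped a replicate 2 peak (12.5% against 12.9%, permutation p = 0.6065), and 4 of 10 the other way (40% against 54.2%, permutation p = 0.9063). At folds as low as those of replicate 1, the depth of replicate 2 could have called 0 of the 72 peaks (smallest callable fold 1.27, median), so depth alone left little room for overlap in that direction. In the other direction, the depth of replicate 1 could have called all 10 replicate 2 peaks at the same fold (smallest callable fold 1.04, median). If folds were the same, depth therefore does not account for those that overlapped no replicate 1 peak. At the only plastid summits of the lists within 50 bp of each other, at 105692 and 105708, fold was 1.04 in replicate 1 and 2.39 in replicate 2. Neither list held a mitochondrial peak.

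**Figure D3:**
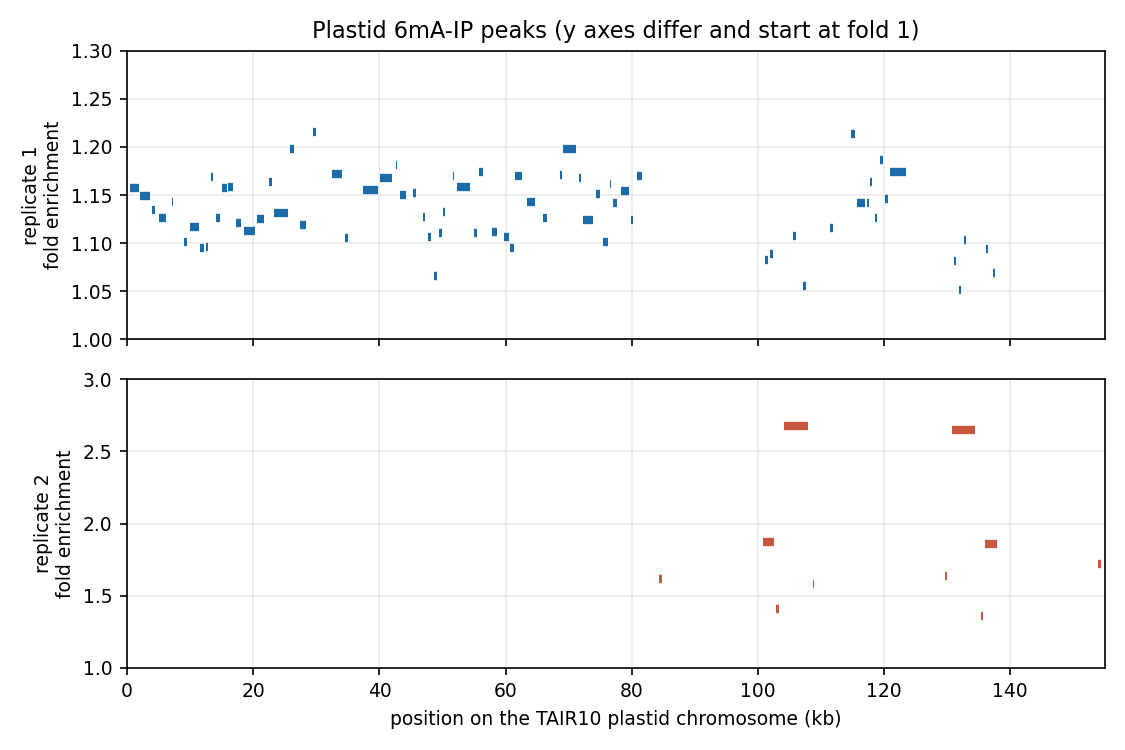
Plastid peaks of replicate 1 (upper panel) and replicate 2 (lower panel). The x axis is the TAIR10 plastid position in kb and the y axis the authors' fold enrichment over input, with a different range in each panel, and each bar spans 1 peak. Replicate 1 has 72 peaks with folds of at most 1.22, and replicate 2 has 10 with folds up to 2.67.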

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

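The tests in this part were all chosen after the plastid peaks had been seen. Both patterns lie in plastid DNA, outside the nuclear comparisons, and no biological explanation was tested for either, since the design names none.

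In replicate 2, peaks covered 98.6% of the bases of the plastid rRNA genes, and 34 of 15435 rotations of the peaks covered as much (permutation p by rotation = 0.0022). The genes rrn16S, rrn23S and rrn4.5S were covered in full, with folds of up to 1.87 in rrn16S and 2.67 in rrn23S, and parts of rpl2, trnI and trnA were covered too. The remaining rRNA gene of the table, ArthCr091 (121 bp), was not covered. The extra copies of the inverted repeat, which holds these genes, are argued against, because peaks covered 3.21% of the bases of its protein-coding genes. Reads of bacterial DNA placed on these conserved genes may be a source and would need such cover, but any other cause specific to rRNA genes predicts the same, and no read was examined. In replicate 1 the rRNA genes were covered over 38.8% of their bases, against a median of 35.1% over rotations (permutation p by rotation = 0.39).

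In replicate 1, peaks covered 65.4% of the bases of single-copy plastid protein-coding genes and 20.4% of the bases between genes. The difference of 45.0 percentage points was reached in 3 of 10485 rotations (permutation p by rotation = 0.00029). Of 75 such gene entries, 56 were covered over more than 50% of their length, among them psbA, matK, atpB, psbB and rbcL. Another 16, among them both ycf1 entries and rps3, were not covered. These counts are of entries and not of distinct genes, since rps12 and ycf1 each enter more than once. Replicate 2 peaks touched 0 of the 75, but at the folds of replicate 1 (median 1.13) its depth could have called 0 of the 72 replicate 1 plastid peaks (smallest callable fold 1.27, median). Saturation of the input by the removal of duplicates would raise folds where the input is deepest. The median fold in the inverted repeat differed from that in single-copy DNA by -0.0594 (9 and 63 peaks, permutation p = 3e-05), the other direction. This does not decide the question. The repeat holds 1 sequence in 2 copies, so its peaks are not independent. Smaller folds can also be called where the background is deeper, here 247 against 144 times the mean coverage. Nor does it compare genes with the bases between them. Base composition, which often differs between plastid genes and the DNA between them, could give this pattern and cannot be told apart from an effect of the genes themselves, because no sequence was used here.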

How the results depend on the processing

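Rotation, loci, regions covered by both lists, rRNA regions left out and the partial correlation were chosen after the data were seen; the other alternatives were planned. The planned union of both lists was the region set itself and tests nothing, so its 6 values are left out. Of the other 56 alternatives for 9 results, 43 kept direction and side of the threshold or, for a count, stayed within 1.5 times (stricter peaks gave 4 chromosomes in place of 3), among them all for overlap and pericentromeric share (64.7% to 93.8%). Without regions in pericentromeres, rho was 0.9 over 5 regions and no longer passed (exact permutation p = 0.0833), the share in genes was 36.8% and no longer passed, and the share between genes, also 36.8%, fell just under the random 37.7%. Placement within 1 Mb ended the call for genes at 6.83%. With either replicate left out, chromosomes past the test ranged from 1 to 5, the share on chromosome 5 from 23.0% to 62.6%, and gene lists past the test from 0 to 1. Regions covered by both lists gave 1 chromosome and 29.6% on chromosome 5, loci gave 0 chromosomes and 17.6%, now below the length share of 22.6%, and peak bases gave 45.4%. The loss on loci comes with 17 in place of 161 units and, on chromosome 5, with 1 locus that held 84 of the 87 replicate 2 peaks there. For the other alternatives the cause was not tested. Correlation under reciprocal overlap could not be run, with too few regions. The planned tests of A+T content, motifs, tandem repeats and transcription starts, with 29 alternatives, were not run. No paired analysis was possible because the input and the immunoprecipitated group share fewer than 2 replicate numbers. Replicate 2, with 995366 fragments, is the shallower side of each comparison between the lists.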

Other observations

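The descriptions and tests in this part were all chosen after the data had been seen. Most nuclear peaks of replicate 2 stood on a low implied input background. At those peaks this background was never below the mean coverage (lowest 1.00 times), so it is not a direct measure of input depth. At 99 of its 139 nuclear peaks the implied input background was under 5 times the mean coverage (median 1.78 times), with folds of 2.56 to 12.5 (median 5.33) on a median pileup of 21 fragments. Of these peaks, 76 were on chromosome 5 and 18 on chromosome 4, and 0 overlapped a replicate 1 peak. The other 40 stood on a median background of 103 times the mean, and 27 of them overlapped replicate 1.

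Most of the low-background peaks formed 4 dense blocks. On chromosome 4 at 2920745 to 2964640, 17 peaks (median fold 5.63) included 1 in the protein-coding gene AT4G05612, near one end of the block, and the others overlapped no annotated gene. On chromosome 5, 30 peaks at 11852465 to 11903326 (median fold 5.36) covered 51.0% of a stretch with 0 annotated genes. Next to it, 19 peaks at 11928311 to 11971102 (median fold 5.85) shared their stretch with 3 pseudogenes and the microRNA gene MIR854e, and 14 peaks at 12026158 to 12065252 (median fold 5.36) shared theirs with 5 pseudogenes. Replicate 1 had 0 peaks in these blocks. The gene table held 0 transposable element genes, so any such genes in these stretches went uncounted.

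The fold was far higher in the shallow replicate 2 than in replicate 1 at the same positions. Saturation of replicate 1 by the removal of duplicates would bring the ratio of folds to about 1 at weaker, unsaturated summits. Outside rRNA loci, 13 summit pairs had a replicate 1 pileup under 4592, against a highest of 45916. Their median ratio was 10.03 (range 6.00 to 13.3, bootstrap 95% interval 7.52 to 11.9). Over all 64 pairs outside rRNA loci the median was 12.5. Several of the 13 pairs share a locus, so the interval is too narrow. Their replicate 1 pileup was still at least 54.7 times the mean coverage, so saturation there was not excluded and the test does not decide this cause. A single scaling factor between the lists is argued against, since the ratio at the 4 regions by rRNA genes was 1.27 and below all 23 others. A different yield of the pull-down, or a difference between the seedlings, may remain, and neither was tested.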
